A study of Rattus norvegicus with 9 samples.

How the data were processed

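Kidneys of 9 rats in 3 groups of 3 (control, CIAKI and CIAKI with icariin) were flash frozen and RNA was taken with Trizol, per the labels. Libraries were made from total RNA with an Illumina TruSeq kit, per the labels. The series design states that the 3 rats of a group were separate animals, so the spread between libraries is that between rats. Per the submitters' processing notes, Bowtie 0.12.2 and the genome build mm8 were used. That build is a mouse genome, while the deposited identifiers are rat Ensembl genes, so which reference was aligned to is not settled by the sources used here. The counter, filters and annotation release are not given in the sources used here.

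The main table was deposited in CPM: all libraries summed to the same total, and the values of a library were whole multiples of 1 step. Whole reads were recovered from those steps for 100% of values (within 0.1 of a whole number), and the recovered reads equalled all 23850 read counts that the authors deposited for selected mRNAs. By those steps, 1 CPM was 73, 69.6 and 75.7 reads in control, 83.2, 67.3 and 64.4 reads in CIAKI and 65.3, 70.6 and 90.4 reads in icariin libraries. The table held 36267 features, 22050 Ensembl genes and 14217 assembled genes, of which 4415 were 0 in all libraries. The symbols of 25 genes had been turned into spreadsheet dates, and these genes entered the tests under their Ensembl identifiers and are not named. The authors' tables of selected mRNAs and lncRNAs hold read counts and FPKM, per the file headers, and those of circRNAs and miRNAs hold read counts and values that the file headers call TPM. Those deposited TPM values were each the read count times a constant per library, with no length term.

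The design fixed before the data were examined had a branch for counts and a branch for normalised values. Since the deposited main table is in CPM, the second branch was used, limma with an intensity trend on log2(CPM + 1). It was run on the 16731 features with at least 1 CPM in at least 3 libraries (13441 Ensembl and 3290 assembled genes). The fit had group as the factor and held all 9 libraries, so that the groups share an estimate of the spread. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with calls at an adjusted p below 0.05. As an alternative added after seeing the data, edgeR's quasi-likelihood test on the recovered reads called 7028, 6745 and 76 genes in the 3 comparisons.

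A total of 39 gene lists with 562 genes was fixed before the data were examined, with 1 gene (Lcn2) in more than 1 list. They cover kidney segments and cells (proximal tubule, thick ascending limb, distal and connecting tubule, principal cell, intercalated cell, podocyte, endothelial, mesenchymal), other cells and tissues (macrophage, neutrophil, lymphocyte, erythroid, adrenal cortex, adipocyte). Others cover injury and stress (tubular injury, matrix remodelling, inflammatory cytokines, interferon, hypoxia, NRF2, unfolded protein response, heat shock, p53, cell cycle, cell death, ferroptosis and iron, immediate early, osmotic stress). The rest cover metabolism (fatty acid oxidation, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, sterol synthesis) and signalling (angiotensin system, nitric oxide and cyclic GMP, aryl hydrocarbon receptor, circadian clock, glucocorticoid response). A sex-linked list served as a check only: Kdm5d stood at 40.2 to 49.5 CPM and Eif2s3y at 58 to 78.2 CPM in all 9 libraries. The 36 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over lists. With an estimated correlation camera called 0 lists in each comparison, with 3, 5 and 4 lists at an unadjusted p below 0.05, and fry, which tests whether a list's own genes move one way, called 21, 18 and 3.

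Named genes followed a rule fixed before the data were examined: per comparison and direction, up to 8 called genes with the largest log2 fold change whose groups did not overlap and whose mean was at least 1 CPM. It added up to 3 members of each list with the smallest p, the genes Havcr1, Lcn2, Clu, Spp1, Timp1, Hmox1, Umod, Slc34a1 and Lrp2, and up to 3 features per direction of each of the authors' tables. List members that moved against their list were named after their values were seen. Genes with near-identical copies (haemoglobin, metallothionein and ribosomal protein genes) are uncertain, since the handling of shared reads is not given in the sources used here. No strand setting is given either, so overlapping genes could not be told apart.

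The test was tested on simulated data for the comparison of CIAKI with control, with 16731 genes of which 200 were changed. It called 13.4% of genes changed 1.5-fold, 50.8% of those changed 2-fold and 84.4% of those changed 4-fold, 3% of calls were unchanged genes, and camera called 10 of 10 shifted and 0 of 36 unchanged sets. Far fewer genes were changed than the 41.3% called in the real comparison, so these shares may not hold there. The simulated genes were drawn independently of each other, while the estimated correlation within the real lists ran from -0.052 to 0.902. The set result therefore says nothing about lists whose genes move together. Alternatives were quantile and upper-quartile scaling, no filter and a stricter filter at 5 CPM, a pseudocount of 0.1, limma without the trend, and the replicate number as a block. Others were genes with Ensembl identifiers only, the 2 groups compared only, each library left out in turn, other thresholds and other set tests. Those added after seeing the data were edgeR, DESeq2 and voom on recovered reads and a rescaling without mitochondrially encoded genes. Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. The selected tables hold features chosen on these libraries, so they were described with no new test. No genome was used here, and no coordinates were converted.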

Results

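RNA from the kidneys of 9 rats was sequenced in 3 groups of 3 rats each. Control rats had no treatment. Rats of the group with contrast-induced acute kidney injury (CIAKI) were given furosemide, a loop diuretic, at 200 mg/kg into the stomach and were dehydrated for 6 h. They then received iopromide, an iodinated X-ray contrast medium holding 370 mg I/mL, into a vein at 15 mL/kg. The icariin group went through the same protocol after icariin, a flavonoid glycoside of Epimedium plants, had been given daily for 3 days at 100 mg/kg. The gene table held 36267 features, of which 16731 were tested. Values are in CPM, read counts scaled to the same library total, and 1 CPM stood for 64.4 to 90.4 reads, depending on the library. On the first principal component (53.6% of the variance) the CIAKI libraries lay at 60.1, 58.5 and 44.4, the control libraries at -29.7, -31.7 and -28.1 and the icariin libraries at -24.6, -26.8 and -22. The second component (9.5%) placed the control libraries at 14.2 to 24.1 and the icariin libraries at -17.3 to -23.2.

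**Figure D1:**
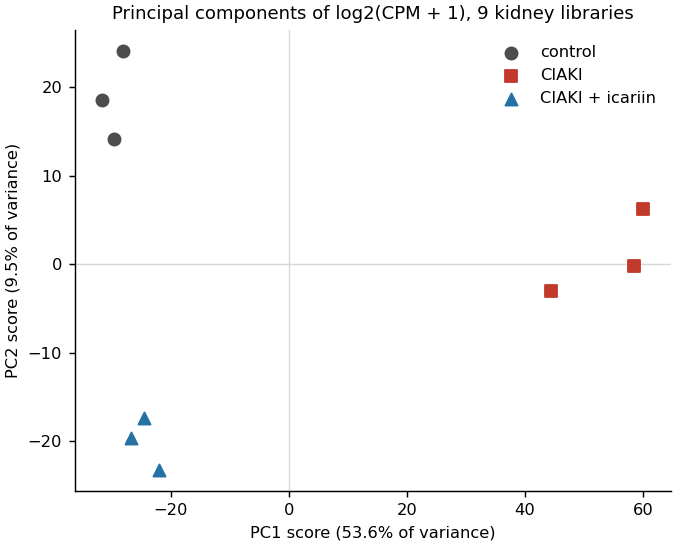
Scores of the 9 libraries on the first principal component (x axis, 53.6% of the variance) and the second (y axis, 9.5%) of log2(CPM + 1) values, each point a library. The 3 CIAKI libraries lie at 44.4 to 60.1 on the first component, apart from the control and icariin libraries at -31.7 to -22.

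The first comparison asked what the contrast protocol does to kidney RNA. In CIAKI kidneys, most tested genes of tubular injury rose. Most tested genes of the proximal tubule, of podocytes, of the cell cycle and of lymphocytes fell. Camera called these lists at its preset correlation only (adjusted p = 0.41 with an estimated correlation, and 0.26 for lymphocyte genes). Havcr1, which encodes the injury receptor KIM-1 of the proximal tubule, went from 0.951 ± 0.375 CPM in control to 464 ± 259 CPM in CIAKI kidneys (SD, n = 3 each), a log2 fold change of 7.76 (SE 0.38, adjusted p = 8.8e-06). Slc34a1, the sodium-phosphate cotransporter of the same segment, went from 4731 ± 453 to 994 ± 210 CPM (log2 fold change -2.27, SE 0.17, adjusted p = 4.7e-05). With limma on log2(CPM + 1) values, 6903 of 16731 genes (41.3%) changed at an adjusted p below 0.05, of which 3479 were higher and 3424 lower in CIAKI. A change of at least 2-fold was found for 1652 of them, 560 higher and 1092 lower. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes with low values.

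Among 20 tubular injury genes, 14 rose, 2 fell and 4 did not pass (15 and 2 adjusted over the list alone), with a median log2 fold change of 0.92 and a camera adjusted p of 6.6e-05 (adjusted p = 0.41 with an estimated correlation). Lcn2, the secreted siderophore-binding protein NGAL, rose from 2.56 ± 0.306 to 56.2 ± 27.2 CPM (3.88, SE 0.34, adjusted p = 8.6e-05). Spp1, which encodes osteopontin, rose by 3.55 (SE 0.51, adjusted p = 0.00083), and the fibrinogen chain genes Fgb and Fga rose by 3.77 and 3.69. Timp1, an inhibitor of matrix metalloproteinases, and Clu, which encodes the chaperone clusterin, rose by 1.35 and 0.67. The members that fell were Vcam1 (-1.12) and Tff3 (-1.18), an adhesion molecule and a trefoil peptide, which were picked out after their values were seen. Other large increases were those of Angptl4, an inhibitor of lipoprotein lipase (5.46, SE 0.45, adjusted p = 6.7e-05), and of Gpnmb (5.05). They were joined by the efflux pump gene Abcc2 (4.81, from 68.4 ± 7.69 to 2018 ± 727 CPM), Igfbp1, which encodes a binding protein of insulin-like growth factors (4.33), and Tnfrsf12a, the receptor of TWEAK (3.78).

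Among 25 proximal tubule genes, 18 fell, 1 rose and 6 did not pass (18 and 2 adjusted over the list alone). Their median log2 fold change was -0.71 with a camera adjusted p of 6.6e-05 (adjusted p = 0.41 with an estimated correlation). Miox, the myo-inositol oxygenase of this segment, lay at -3 on the log2 scale (1968 ± 32.4 to 246 ± 29.2 CPM, adjusted p = 5.1e-06). The organic anion transporter gene Slc22a8 lay at -2.02, and Lrp2, which encodes the endocytic receptor megalin, at -1.19 (SE 0.21, adjusted p = 0.0023). The member that rose was Slc17a3, a transporter of phosphate and urate, at 1.28. Podocyte genes fell too, 10 of 11 with none higher (median -0.69, camera adjusted p = 0.00018, and adjusted p = 0.41 with an estimated correlation). Nphs1 (nephrin) lay at -0.71 and the sialoglycoprotein gene Podxl at -0.57. Egf and Umod, made in the thick ascending limb, lay at -1.84 (SE 0.13, adjusted p = 4.1e-05) and -0.79 (SE 0.21, adjusted p = 0.016). The call of Umod was lost without control 2 (adjusted p = 0.0534). The largest decreases among named genes were those of Prima1, the membrane anchor of acetylcholinesterase (-4.71, SE 0.59), the retinol receptor gene Stra6 (-3.68), Sphkap (-3.56) and Tmem86a (-3.51). Next came Cacng5, which encodes an ion channel subunit (-3.51), the guanylate cyclase subunit gene Gucy1b2 (-3.3), the gelatinase gene Mmp9 (-3.17) and Rgn, which encodes regucalcin (-3.14).

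**Figure D2:**
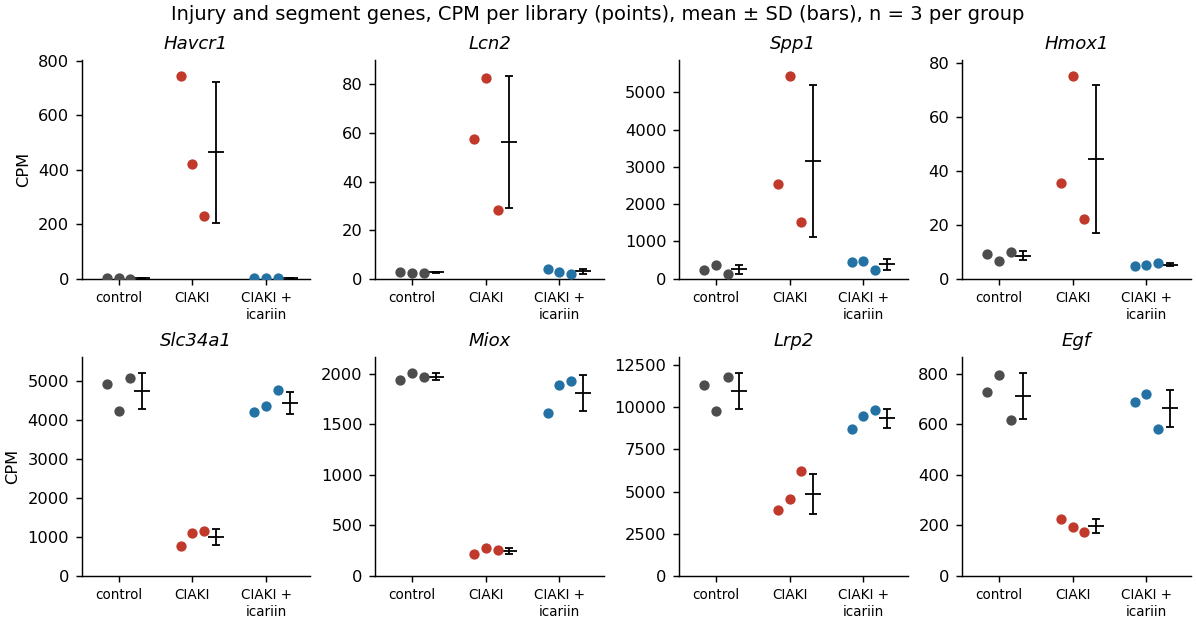
CPM (y axes, from 0) of 4 injury genes and 4 tubule genes in each library of the 3 groups (points), with bars for the mean ± SD (n = 3). Havcr1 had means of 0.951 CPM in control, 464 in CIAKI and 2.18 in icariin kidneys, and Slc34a1 had 4731, 994 and 4424.

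Cell cycle genes fell in CIAKI kidneys, 11 of 17 with 6 not passing (12 lower and 1 higher adjusted over the list alone; median -0.75; camera adjusted p = 0.00029; adjusted p = 0.41 with an estimated correlation). Among them were the topoisomerase gene Top2a at -3.02 and the proliferation marker Mki67 at -2.2. All 6 lymphocyte genes tested, of 14 in the list, fell (median -1.09, camera adjusted p = 0.0013, and adjusted p = 0.26 with an estimated correlation). The T cell kinase gene Lck lay at -1.27 and the cytotoxic granule gene Nkg7 at -1.23. Of 17 nuclear genes of oxidative phosphorylation, 9 fell, 1 rose and 7 did not pass (12 and 1 adjusted over the list alone; median -0.25; camera adjusted p = 0.003; adjusted p = 0.41 with an estimated correlation). Cycs (cytochrome c) lay at -0.91, the complex I gene Ndufs1 at -0.48 and the succinate dehydrogenase gene Sdha at -0.44, while Cox5a rose by 0.18. The Cox5a call ended with 15 of 22 alternatives, among them upper-quartile scaling (adjusted p = 0.207) and leaving out control 3 (0.156).

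Cytosolic ribosomal protein genes rose, 23 of 24 with a median of 0.63 (camera adjusted p = 4.5e-11, and adjusted p = 0.41 with an estimated correlation). Rplp0 and Rpl8 lay at 1.07 and 0.78, although reads of such genes can be shared with their many processed copies. Of 16 p53 targets, 10 rose, 1 fell (Rrm2b, -0.75) and 5 did not pass (median 0.6, camera adjusted p = 0.0057, and adjusted p = 0.26 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose by 2.71 and the secreted stress factor gene Gdf15 by 2.21. Of 14 genes of ferroptosis and iron handling, 8 rose and none fell (median 0.28, camera adjusted p = 0.0032, and adjusted p = 0.3 with an estimated correlation). They included Acsl4, an acyl-CoA synthetase that makes lipids prone to peroxidation (1.19), the ferritin heavy chain gene Fth1 (1.16) and the ferritinophagy receptor gene Ncoa4 (1.12). Of 17 genes of the unfolded protein and integrated stress response, 6 rose and none fell (median 0.29, camera adjusted p = 0.0068, and adjusted p = 0.41 with an estimated correlation), with Asns at 1.46 and Atf4 at 1.34. Of 10 heat shock genes, 5 rose (median 0.36, camera adjusted p = 0.037, and adjusted p = 0.48 with an estimated correlation), among them Hsp90aa1 at 1.24. The heat shock call ended with quantile normalization (adjusted p = 0.096) and without control 2, CIAKI 2 or CIAKI 3 (0.054, 0.069 and 0.077).

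Of 11 glucocorticoid response genes, 6 rose, 1 fell (Klf9, -0.45) and 4 did not pass (median 1.04, camera adjusted p = 0.0041, and adjusted p = 0.41 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 2.64 and the metallothionein gene Mt2A by 1.8. Lcn2 belongs to this list as well. Of 18 fatty acid oxidation genes, 8 rose, 1 fell (Ppara, -0.61) and 9 did not pass (median 0.33, camera adjusted p = 0.0064, and adjusted p = 0.73 with an estimated correlation). The Ppara call ended with edgeR on recovered reads (0.0539) and without any control library, CIAKI 1 or CIAKI 2 (up to 0.0838). The carnitine palmitoyltransferase genes Cpt1a and Cpt2, whose products bring fatty acids into mitochondria, rose by 1.28 and 1.29. Of 14 NRF2 antioxidant genes, 8 rose, 1 fell (Osgin1, -1.14) and 5 did not pass (median 0.74, camera adjusted p = 0.061). The cystine transporter gene Slc7a11 lay at 3.43 and Hmox1, which encodes haem oxygenase, at 2.09 (SE 0.36, adjusted p = 0.002). Of 6 erythroid genes 4 rose in the limma test (5 adjusted over the list alone; median 2.14; camera adjusted p = 0.059), against 1 in edgeR and 3 in DESeq2 on recovered reads. Control 1 stood apart from the other controls in these genes, with a list median of 1.6 against -0.77 and -0.72, near the CIAKI libraries at 1.9 to 2.23. The globin gene Hbb stood at 183 ± 189 CPM in control and 721 ± 94.3 CPM in CIAKI kidneys (2.46, SE 0.79, adjusted p = 0.032). The Hbb call ended when control 2, control 3 or any CIAKI library was left out (adjusted p up to 0.107).

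The second comparison asked how kidneys differed when icariin had been given before the contrast protocol. Most tubular injury and ribosomal protein genes were lower and most proximal tubule, oxidative phosphorylation, podocyte and cell cycle genes were higher in icariin than in CIAKI kidneys. Camera called these lists at its preset correlation only (adjusted p = 0.3 to 0.62 with an estimated correlation). Havcr1 stood at 2.18 ± 0.717 CPM in icariin kidneys (log2 fold change -7.06 against CIAKI, SE 0.38, adjusted p = 1.2e-05) and Slc34a1 at 4424 ± 291 CPM (2.17, SE 0.17, adjusted p = 7.1e-05; n = 3 per group). In all, 6592 of 16731 genes (39.4%) changed in the limma test, 3219 higher and 3373 lower with icariin. Of these, 1410 changed by at least 2-fold, 902 higher and 508 lower.

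Among the 20 tubular injury genes, 13 fell, 2 rose (Tff3 at 1.14 and Vcam1 at 0.5) and 5 did not pass (14 and 2 adjusted over the list alone; median -1.02; camera adjusted p = 1.6e-05; adjusted p = 0.36 with an estimated correlation). The Vcam1 call ended without CIAKI 1 (0.0756), icariin 2 (0.104) or icariin 3 (0.058). Lcn2 lay at -3.73 (SE 0.34, adjusted p = 0.00013), Fgb at -4.33, Spp1 at -2.91 (SE 0.51, adjusted p = 0.0024), Timp1 at -1.46 and Clu at -0.98. Other large decreases were those of Abcc2 (-4.81), Gpnmb (-4.65), Ugt2a3, which encodes a glucuronosyltransferase (-4.6), Tnfrsf12a (-4.19) and the adhesion receptor gene PVR (-3.8). Of 25 proximal tubule genes, 19 rose, 1 fell (Slc17a3, -2.06) and 5 did not pass (median 0.9, camera adjusted p = 2.7e-06, and adjusted p = 0.3 with an estimated correlation). Miox rose by 2.88, Slc22a8 by 2.21 and Lrp2 by 0.96 (SE 0.21, adjusted p = 0.0068). Of 11 thick ascending limb genes 3 rose and 8 did not pass (median 0.22, camera adjusted p = 0.19), with Egf at 1.74 and Umod at 0.97. The largest increases among named genes were those of Prima1 (4.53, SE 0.59), Cacng5 (3.36), Spata22 (3.25) and Dmrtc1c1 (3.2). Next came the oestrogen receptor gene Esr1 (3.16, from 18.4 ± 7.72 to 163 ± 8.33 CPM), Gucy1b2 (3.09), Sspo (3) and the aldehyde dehydrogenase gene Aldh1b1 (2.97).

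Of 17 oxidative phosphorylation genes, 12 rose and none fell with icariin (13 adjusted over the list alone; median 0.34; camera adjusted p = 0.00032; adjusted p = 0.31 with an estimated correlation). Sdhb lay at 0.5 and Sdha at 0.43. Beside this group, icariin 2 stood apart in the mitochondrially encoded gene Mt-co1, at 437 CPM against 22773 to 38157 CPM in the 8 other libraries. Mitochondrially encoded genes took 1.65% of its reads against 3.86% to 5.71% in the others. Mt-co3 was lowest in icariin 1, at 143 CPM against 603 to 3776 CPM. Podocyte genes rose, 7 of 11 with none lower (median 0.36, camera adjusted p = 0.0078, and adjusted p = 0.62 with an estimated correlation). So did cell cycle genes, 9 of 17 with none lower (median 0.47, camera adjusted p = 0.0068, and adjusted p = 0.62 with an estimated correlation), with Top2a at 2.28. Of 6 lymphocyte genes 3 rose (5 adjusted over the list alone; median 0.46; camera adjusted p = 0.035; adjusted p = 0.3 with an estimated correlation). Among them were Lck at 0.84 and Cd4 at 1.12. That list's call ended with quantile normalization (adjusted p = 0.14), upper-quartile scaling (0.053) and without CIAKI 3 (0.058).

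Cytosolic ribosomal protein genes fell, 22 of 24 with a median of -0.59 (camera adjusted p = 8.6e-10, and adjusted p = 0.36 with an estimated correlation), among them Rpl4 at -0.99 and Rplp0 at -0.87. Of 16 p53 targets 9 fell and 1 rose (Rrm2b, 0.81), with Gdf15 at -2.89 and Ccng1 at -0.99 (median -0.59, camera adjusted p = 0.004, and adjusted p = 0.3 with an estimated correlation). Of 14 genes of ferroptosis and iron handling 7 fell and none rose, with Acsl4 at -1.24 and Fth1 at -1.1 (median -0.36, camera adjusted p = 0.0057, and adjusted p = 0.3 with an estimated correlation). Of 14 NRF2 antioxidant genes 8 fell and 1 rose (Osgin1, 1.53), with the aldo-keto reductase gene Akr1b8 at -3.61 and Hmox1 at -2.71 (median -0.9, camera adjusted p = 0.014, and adjusted p = 0.57 with an estimated correlation). Of 8 aryl hydrocarbon receptor and xenobiotic genes 4 fell and 1 rose (Cyp1a1, 2.22), with the drug efflux pump gene Abcb1a at -1.8 (median -1.18, camera adjusted p = 0.018, and adjusted p = 0.3 with an estimated correlation). The Cyp1a1 call ended with edgeR on recovered reads (0.11) and without CIAKI 2, CIAKI 3, icariin 2 or icariin 3 (up to 0.0675). Myc, which had risen by 3.16 in CIAKI, lay at -2.98.

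**Figure D3:**
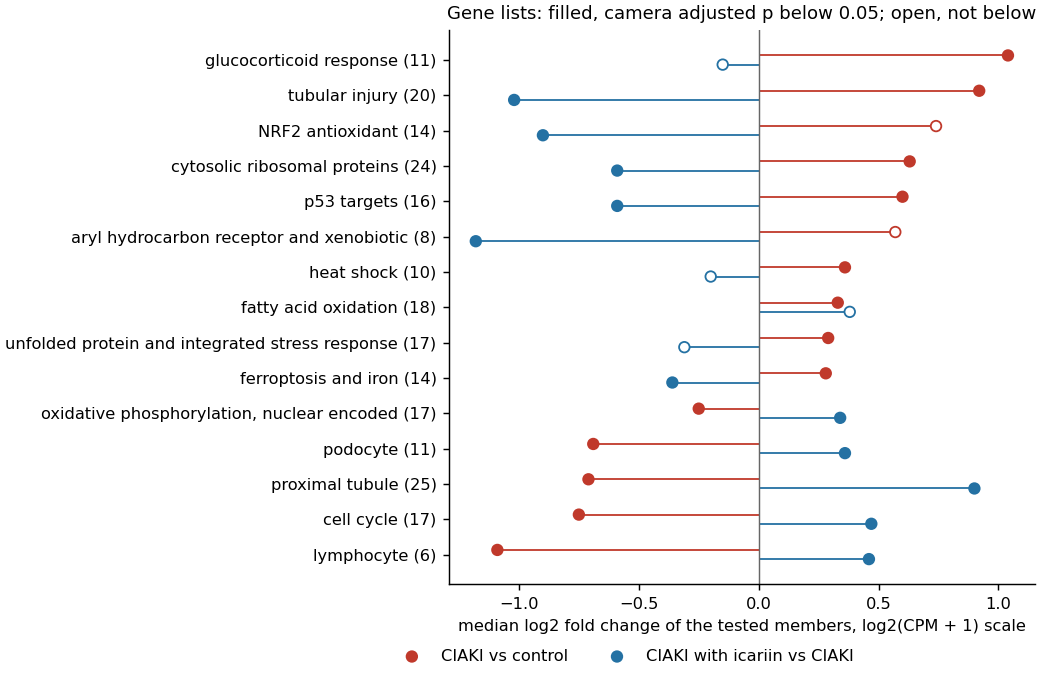
Median log2 fold change (x axis, log2(CPM + 1) scale) of the tested members of each gene list (y axis, number of members in brackets) in CIAKI against control and in icariin against CIAKI kidneys, for the lists with a camera adjusted p below 0.05 in either comparison (filled points). Open points are not below 0.05; tubular injury genes lie at 0.92 and -1.02 and proximal tubule genes at -0.71 and 0.9.

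Of the 6903 genes changed by CIAKI, 5429 (78.6%) changed in the opposite direction with icariin and 6 in the same direction. Against control, 68 of the 6903 still differed in the CIAKI direction in icariin kidneys, in a comparison that called only 105 genes in all. Of 1705 genes changed by CIAKI at an unadjusted p below 0.05 and at least 2-fold, 362 still differed from control in the CIAKI direction. Another 44 differed in the opposite direction, both counted at an unadjusted p below 0.05 in the limma test. The mean shift of the 6903 genes went back by 87.7% with icariin, 90.9% for genes higher and 85.2% for genes lower in CIAKI. The CIAKI libraries enter both comparisons with opposite sign, so some opposite calls and part of a negative correlation between the comparisons arise by construction. The 87.7% was measured on the same libraries that chose the genes. Across genes, the log2 fold changes correlated at -0.89, against -0.5 in 100 simulations of unchanged groups. Their covariance was -0.371 against -0.025, a difference of -0.346. Independent lists of the same sizes would share 1360 genes with opposite signs. When genes were chosen with 2 control and 2 CIAKI libraries and the shift was measured from the left-out ones, the return was 90.7% on average over 9 such choices (89.1% to 92.7%). Each of these choices gave a return above 87.7%.

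The third comparison asked whether kidneys given icariin and contrast differed from untreated kidneys. In icariin kidneys 6 of 18 fatty acid oxidation genes, 3 of 11 glucocorticoid response genes and 5 of 16 clock genes rose, and 3 clock genes and the calcium-binding gene Calb1 fell. Camera called the 3 lists at its preset correlation only (adjusted p = 0.21, 0.24 and 0.076 with an estimated correlation). Directional fry called the fatty acid oxidation and clock lists (adjusted p = 0.017 and 0.0055) but not the glucocorticoid response list (0.056). Cyp4a1, which encodes a fatty acid hydroxylase, went from 71.5 ± 8.7 CPM in control to 213 ± 19.6 CPM in icariin kidneys (SD, n = 3 each; log2 fold change 1.56, SE 0.15, adjusted p = 0.0051), with 140 ± 28.4 CPM in CIAKI kidneys. In all, 105 of 16731 genes (0.6%) changed in the limma test, 67 higher and 38 lower with icariin, and 47 of them by at least 2-fold. Without control 1, 2 or 3 the count was 38, 31 or 31, and without icariin 1, 2 or 3 it was 61, 31 or 41.

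Of 18 fatty acid oxidation genes, 6 rose, none fell and 12 did not pass, while 16 rose adjusted over the list alone (median 0.59, camera adjusted p = 6.5e-24, and adjusted p = 0.21 with an estimated correlation). Besides Cyp4a1, these included Cpt1a at 0.81 (SE 0.12, adjusted p = 0.027). In CIAKI against control 8 of the 18 had risen and 1 had fallen, with Cpt1a at 1.28. Between icariin and CIAKI 8 rose and 2 fell, and camera did not call the list (adjusted p = 0.16). Other genes higher in icariin than in control kidneys were Angptl4 (3.32, SE 0.45, adjusted p = 0.019, and 5.46 in CIAKI against control), the transcription factor gene Creb3l3 (2.28), and the pantetheinase gene Vnn1 (2.06). Further ones were Eci1, which encodes an enoyl-CoA isomerase (1.91, SE 0.2, adjusted p = 0.0057), and the acyl-CoA synthetase gene Slc27a2 (0.83). Of 11 glucocorticoid response genes 3 rose (4 adjusted over the list alone; median 0.31; camera adjusted p = 1e-05; adjusted p = 0.24 with an estimated correlation). These were Fkbp5 at 1.73 (SE 0.17, adjusted p = 0.0051), Zbtb16 at 2.85 (SE 0.34, adjusted p = 0.012) and Tsc22d3 at 1.01. They had risen in CIAKI against control too, by 2.64, 3.01 and 1.04. The vasopressin-regulated water channel gene Aqp2 rose by 1.26 and the angiopoietin receptor gene Tek by 0.54.

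Of 16 circadian clock genes, 5 rose, 3 fell and 8 did not pass (10 and 3 adjusted over the list alone; median 0.61, mean 0.2; camera adjusted p = 0.00016; adjusted p = 0.076 with an estimated correlation). Npas2 and Arntl, whose products are transcriptional activators of the clock, lay at -2.1 (adjusted p = 0.0057) and -1.55 (SE 0.19, adjusted p = 0.012). Arntl went from 14.6 ± 1.19 to 4.42 ± 1.38 CPM. The clock repressor gene Cry1 rose by 1.17 (SE 0.13, adjusted p = 0.0057), and in CIAKI against control by 1.75. Calb1 of the distal tubule stood at 566 ± 41.2 CPM in control, 219 ± 18.9 in CIAKI and 226 ± 28.7 in icariin kidneys (-1.32 between icariin and control, SE 0.11, adjusted p = 0.0029). Further decreases were those of Psph of serine synthesis (-1.43), Csmd1 (-1.41), Tdrd5 (-1.3), the monocyte chemokine gene Ccl2 (-1.29), Apln, which encodes the peptide apelin (-1.19), and Slc17a3 (-0.79). The calls of Vnn1, Eci1, Fkbp5, Npas2, Calb1, Cyp4a1 and Cry1 held under all of the 22 alternative settings in which the gene was tested. Leaving out a single library ended the calls of Angptl4 (adjusted p = 0.0971 without control 3), Arntl (0.0696 without control 2), Cpt1a (0.122 without control 3), and Csmd1 (0.0573 without icariin 2). It also ended those of Creb3l3 (0.131 without control 1), Tsc22d3 (0.131 without control 1), Aqp2 (0.125 without control 1), and Tek (0.117 without control 1). Further calls that ended were those of Slc27a2 (0.144 without control 3), Psph (0.124 without control 3), and Ccl2 (0.188 without control 3). The remaining ones were those of Apln (0.0767 without control 2), Slc17a3 (0.0696 without control 2) and Tdrd5 (0.0671 without control 2). The call of Zbtb16 ended with voom on recovered reads (0.0735).

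**Figure D4:**
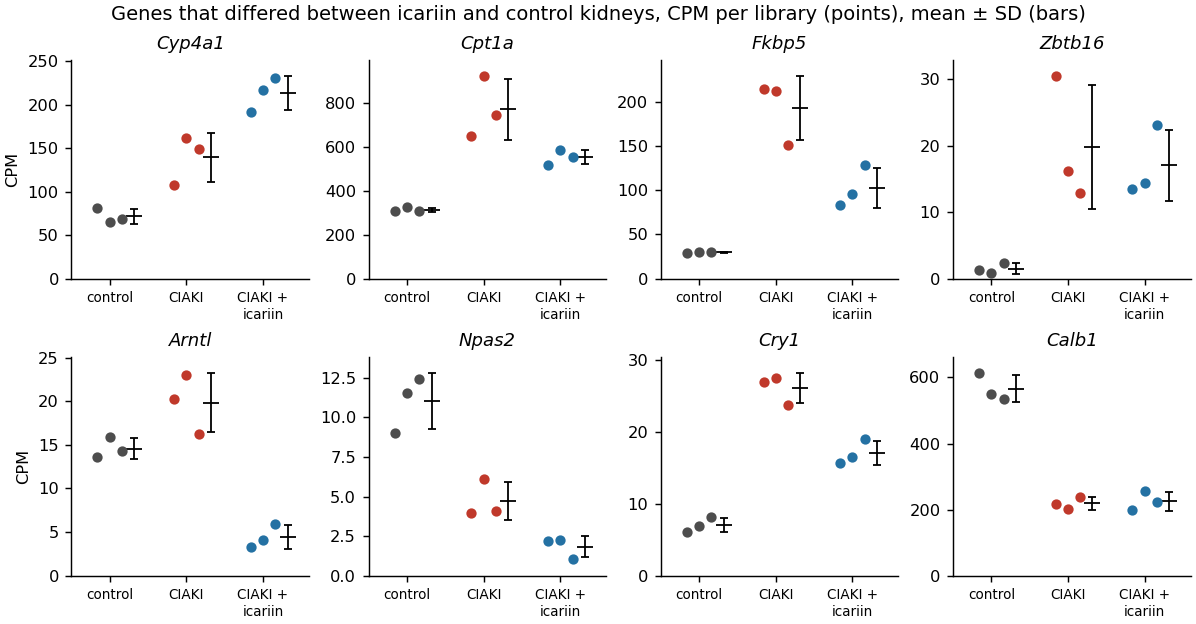
CPM (y axes, from 0) of 8 genes that differed between icariin and control kidneys in each library (points), with bars for the mean ± SD (n = 3). Cyp4a1 had means of 71.5 CPM in control, 140 in CIAKI and 213 in icariin kidneys, and Arntl had 14.6, 19.8 and 4.42.

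Tubular injury genes did not pass in this comparison, 0 of 20 in the limma test (2 at an unadjusted p below 0.05, 0 in edgeR and 1 in DESeq2 on recovered reads), with a median of -0.01 and a camera adjusted p of 0.77. Havcr1 stood at 0.69 (SE 0.38, adjusted p = 0.61), Spp1 at 0.64, Lcn2 at 0.15 and Hmox1 at -0.62, and Slc34a1 at -0.09 (SE 0.17, adjusted p = 0.92). Of 25 proximal tubule genes 1 rose and 1 fell (median 0.11, camera adjusted p = 0.54). Several lists were called by camera on small shifts with few or no members passing. Lymphocyte genes had a median of -0.44 (5 of 6 lower adjusted over the list alone; camera adjusted p = 1e-04; adjusted p = 0.076 with an estimated correlation). Cell cycle genes had one of -0.34 (7 of 17 lower adjusted over the list alone; camera adjusted p = 0.00016; adjusted p = 0.51 with an estimated correlation) and sterol synthesis genes one of -0.32 (5 of 15 lower adjusted over the list alone; camera adjusted p = 0.00016; adjusted p = 0.45 with an estimated correlation). Distal tubule genes, to which Calb1 belongs, had a median of -0.4 (4 of 7 lower adjusted over the list alone, camera adjusted p = 0.00067, and adjusted p = 0.4 with an estimated correlation). Matrix genes lay at a median of -0.29 (camera adjusted p = 0.00016), mesenchymal genes at -0.25 (0.00048) and inflammatory genes at -0.37 (0.0019), each with adjusted p = 0.51 with an estimated correlation. Podocyte genes lay at -0.21 (camera adjusted p = 0.00067, and adjusted p = 0.51 with an estimated correlation) and ribosomal protein genes at 0.11 (camera adjusted p = 6e-04, and adjusted p = 0.6 with an estimated correlation). NRF2 genes lay at -0.2 (camera adjusted p = 0.016, and adjusted p = 0.51 with an estimated correlation), and that call ended without control 2 (0.15), icariin 1 (0.076) or icariin 2 (0.055). Principal cell genes lay at 0.06 (camera adjusted p = 0.035, and adjusted p = 0.62 with an estimated correlation) and endothelial genes at 0.18 (camera adjusted p = 0.044, and adjusted p = 0.6 with an estimated correlation). Both calls ended with several alternatives, among them leaving out control 2 (0.15 and 0.2) or icariin 1 (0.15 and 0.17) and quantile normalization (0.051 and 0.063). The endothelial call also ended with the replicate number as a block (camera adjusted p = 0.056). The log2 fold changes of icariin and of CIAKI against the shared control libraries correlated at 0.34 across genes, against 0.5 in simulations of unchanged groups. Their covariance was 0.069 against 0.025, a difference of 0.045. Of the genes called in both, 68 moved the same way and 8 in opposite ways, against 21.7 shared in the same direction by independent lists. The lists are not independent, since the shared control libraries give some calls in the same direction by construction, and that number was not simulated.

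The authors also deposited tables of RNAs selected between the CIAKI and icariin libraries, by a rule that is not given in the sources used here, so that they are no independent evidence of a direction. The authors' deposited mRNA table held 3975 genes, 2381 with a higher and 1594 with a lower mean FPKM in icariin libraries. Of these, 3633 (91.4%) were called in the limma test, 3631 in the same direction. Of the 1410 genes called at least 2-fold, 1391 were in that table. Havcr1 was among the largest decreases there, at 90.4 ± 48.7 FPKM in CIAKI and 0.434 ± 0.139 FPKM in icariin libraries (SD, n = 3), with Cyp3a9, a cytochrome P450 gene (1.84 ± 1.58 and 0.00956 ± 0.0166 FPKM). The lncRNA table held 989 transcripts, 694 higher and 295 lower in icariin, of which 943 carried identifiers of assembled transcripts. The transcript MSTRG.7795.1 was listed at 0 in the CIAKI libraries and at 10.4 ± 1.42 FPKM in icariin libraries (2890, 4146 and 4778 reads).

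The authors' deposited miRNA table held 128 miRNAs, 68 higher and 60 lower in icariin libraries, of which 64 were newly predicted. The predicted miRNAs that led by ratio had at most 18 reads in any library. The miRNA miR-21-5p, which is induced in injured tissue and was chosen after its values were seen, stood at 105000 ± 13720 TPM in CIAKI and 50830 ± 7311 TPM in icariin libraries (SD, n = 3). The circRNA table held 16 circular RNAs, 10 detected in CIAKI libraries alone and 6 in icariin libraries alone, and 4 of them in a single library. On chromosome 1, a circle from 278580846 to 278749829 had 0, 57 and 56 reads in icariin libraries and none in CIAKI libraries. Circles with the same start were also found in CIAKI libraries alone. They ended at 278594581 (59, 36 and 58 reads) and at 278620822 (47, 39 and 0 reads), so circles from this start were found in both groups. Another circle, from 168958579 to 168964665, had 171 reads in CIAKI 3 alone. On chromosome 4, a circle from 66172555 to 66200637 had 21, 11 and 44 reads in icariin libraries, and on chromosome 10 a circle from 13767446 to 13810899 had 82, 115 and 0 reads in CIAKI libraries. The coordinates are the authors', and neither their genome build nor whether they count from 0 or 1 is given in the sources used here.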

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

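The count tools and the rescaling were chosen after the data were seen. The number of changed genes lay within 1.5 times of the reported one with the other scalings, filters, pseudocount and tools and with only the 2 groups compared, at 5781 to 7795 for CIAKI against control and 5512 to 7595 for icariin against CIAKI. It was lower with a minimum of 2-fold, at 1652 and 1410 (1705 and 1450 with an unadjusted p). Leaving out a library gave 5524 to 6853 and 5138 to 6236. The 105 genes of icariin against control became 52 without a filter on low values, 524 with DESeq2 on recovered reads (103 shared) and 47 with a minimum of 2-fold. It was 168 with that minimum and an unadjusted p, and 31 to 127 with a library left out, and the causes were not tested. Upper-quartile scaling moved the share of higher calls from 50.4% to 41.8% and from 48.8% to 57.2% in the first 2 comparisons.

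Camera called 13, 11 and 15 lists at the preset correlation (13 to 16, 10 to 16 and 12 to 17 with a library left out) and 0, 0 and 0 with an estimated one. Directional fry called 21, 18 and 3, which held 13, 11 and 3 of the lists that camera called at the preset correlation. Mixed fry called 32, 31 and 16, and without a filter camera called 18 lists between icariin and CIAKI. The share of CIAKI changes reversed with icariin was 68.4% to 82.6% with a library left out. It was 90.9% for genes chosen by unadjusted p and 2-fold, where the reversal too was counted at an unadjusted p, a lower bar. Of those 1705 genes, 362 still differed from control in the CIAKI direction at an unadjusted p below 0.05 in the limma test. Of 85, 49 and 22 calls of named genes, 5, 2 and 15 ended with at least 1 of 22 alternatives, and no named gene or list turned its direction. The stricter filter tested 150 of these 156 calls, and a call not tested there counted as kept.

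With the replicate number as a block, 6678, 6314 and 73 genes and 13, 11 and 14 lists were called, and 78.1% of changes reversed. No clear pairing by number was seen: deviations of libraries with the same number correlated at -0.035 to 0.081, with 0 pairs over 0.1, and the best match had the same number for 8 of 18. A weak pairing cannot be excluded this way. In data simulated for CIAKI against control, with only 200 of 16731 genes changed, 13.4% of genes changed 1.5-fold were called. No simulation was run with as many changed genes as were called, or with changes between icariin and control.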

Other observations

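The tests of splits were written before the counts of the other splits were seen, though after the number of genes called was known. The other tests of explanations here were chosen, and their bounds set, after the result was seen. The following lists were not described above for CIAKI against control kidneys, and camera called none of them there. Of 8 genes of the angiotensin system 2 rose and 3 fell (camera adjusted p = 0.54), with the receptor gene Agtr1a down from 72.5 ± 2.26 to 29 ± 5.45 CPM (log2 fold change -1.31, limma adjusted p = 0.00016). Of 7 nitric oxide and cyclic GMP genes 2 rose and 3 fell (camera adjusted p = 0.62), with the soluble guanylate cyclase gene Gucy1a1 at -1.98 and the phosphodiesterase gene Pde5a at 0.84. In endothelial genes 1 of 11 rose and 4 fell (camera adjusted p = 0.36), with Ehd3 of glomerular capillaries at -0.98 and the receptor gene Tie1 at -1.16. Macrophage genes went 5 of 11 lower and 1 higher (camera adjusted p = 0.14), with Aif1 at -1.71 and Adgre1 at -1.84, and between icariin and CIAKI 5 rose and 1 fell (camera adjusted p = 0.11), with these at 1.58 and 1.32. Of 12 inflammatory genes 4 rose and 4 fell (camera adjusted p = 0.85), with Ccl2 at -1.47 and Cx3cl1 at -1.1. Cell death genes included a rise of the necroptosis kinase gene Ripk3 (1.7) and of Bcl2l1 (0.67), with 6 of 14 higher and 3 lower (camera adjusted p = 0.23). Between icariin and CIAKI 2 of the 14 rose and 7 fell (camera adjusted p = 0.11), with Ripk3 at -1.98.

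Of 15 immediate early genes 4 rose and 2 fell in CIAKI (camera adjusted p = 0.23), with Myc at 3.16 and Atf3 at 2.25. Of 17 hypoxia genes 4 rose and 4 fell (camera adjusted p = 0.84), with the lactate dehydrogenase gene Ldha at 1.73. Of 14 matrix genes 2 rose and 8 fell (camera adjusted p = 0.23), and of 12 mesenchymal genes 1 rose and 3 fell (camera adjusted p = 0.17), with Col1a1 at -2.26 and the collagen crosslinking enzyme gene Lox at 1.58. Principal cell genes went both ways (3 of 9 higher and 3 lower, camera adjusted p = 0.87). The water channel gene Aqp4 lay at 1.86 and the sodium channel gene Scnn1b at -0.6. Thick ascending limb (4 of 11 lower, camera adjusted p = 0.23), distal tubule (3 of 7 lower, 0.24) and intercalated cell genes (2 of 8 lower, 0.29) had members that fell and none that rose. Members also passed among osmotic stress (2 of 7 higher, 0.84), sterol synthesis (2 of 15 higher and 3 lower, 0.84) and mitochondrially encoded genes (2 of 13 lower, 0.47). Of 5 adipocyte genes 0 passed in the limma test (1 at an unadjusted p below 0.05, 0 in edgeR and 1 in DESeq2 on recovered reads, with a camera adjusted p of 0.42). Of 8 aryl hydrocarbon receptor and xenobiotic genes 4 rose and 1 fell (0.18), and of 16 clock genes 3 rose and 8 fell (0.57), with Dbp at -2.06. Of 16 interferon genes 1 passed (Mx1, camera adjusted p = 0.25). Mx1 stood at 9.56 CPM in CIAKI 1 and at 0.669 and 0.963 CPM in CIAKI 2 and CIAKI 3 against 12.6 to 14.4 CPM in control libraries. Its call ended with edgeR on recovered reads (adjusted p = 0.135) and without any control library, CIAKI 2 or CIAKI 3 (up to 0.0923). The neutrophil and adrenal cortex lists had 1 tested member each, Csf3r at 0.23 (adjusted p = 0.41) and Cyp21a1 at -0.93 (adjusted p = 0.0023). In the authors' deposited miRNA table, the erythroid miR-451-5p stood at 475, 534 and 396 TPM in CIAKI and at 24.3, 269 and 206 TPM in icariin libraries. The globin gene Hbb stood at 67.5, 416 and 397 CPM in the same icariin rats, both lowest in icariin 1.

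With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split, 1 of 10, called 6903, 6592 and 105 genes in the 3 comparisons, and the highest of the other splits called 1, 1 and 11. Every other split mixed libraries of the 2 groups, so a real difference adds to its spread and lowers its count. The low counts of the other splits therefore cannot decide about chance.

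Icariin kidneys lay near control kidneys in the genes that CIAKI changed. An explanation by further untreated kidneys handled like the controls was tested: of the 105 genes that best separated icariin from 2 control libraries, at least 74.3% moved the same way in CIAKI against the left-out control library (up to 77.1%), above the highest of 1000 random sets of directions (69.5%). Genes move together, though, and such random sets understate chance, so this test alone cannot decide. Fatty acid oxidation genes, a list fixed beforehand, had library medians of 0.51 to 0.66 in icariin and -0.04 to 0.03 in control kidneys. For those genes, these values argue against untreated kidneys handled like the controls. Directional fry called that list (adjusted p = 0.017), while camera with an estimated correlation did not (adjusted p = 0.21). It stays open that the contrast medium may not have acted in these rats for a reason other than icariin, since tubular injury genes had a median of -0.01 against control, and no group had furosemide and dehydration without contrast. Handling that the icariin and CIAKI groups shared was not tested, nor was the biological explanation, an effect of icariin itself, apart from the contrast protocol.

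Proximal tubule genes fell in CIAKI kidneys. A lower share of proximal tubule alone would raise other kidney cell types alike, whereas podocyte genes fell to a median of -0.69. Those genes cannot decide the question, since less cortex would lower both lists, and this explanation stays open. Scaling by library totals was argued against by a proximal tubule median of -0.78 with upper-quartile scaling. A lower share of cortex stays open: thick ascending limb genes had a median of -0.27 with 4 of 11 lower and none higher, but their library medians overlapped (-0.26 to -0.05 in CIAKI and -0.26 to 0.26 in control). Podocyte genes fell, as less cortex would give, while collecting duct genes did not rise as a set, with principal cell genes going both ways (median -0.32, 3 of 9 higher and 3 lower, with Aqp4 at 1.86, Aqp2 at 0.9 and Scnn1b at -0.6) and 2 of 8 intercalated cell genes lower and none higher. A lower expression within injured tubules stays open too and was not tested at the level of cells.

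Clock genes differed between icariin and control kidneys in opposite ways. A candidate explanation is that kidneys were taken at another time of day, since genes driven by BMAL1 had a median of 0.73 (11 genes, 4 higher) and genes repressed by REV-ERB one of -0.5 (5 genes, 3 lower and 1 higher), a difference of 1.23. Between icariin and CIAKI the sets lay at 1.14 (9 of 11 higher) and -1.02 (5 of 5 lower), and between CIAKI and control at -0.42 and 0.41, and the same doubt applies there. Such differences would also arise from an effect of the treatment on the clock, and the time of sampling is not given in the sources used here, so the time of day and the treatment cannot be told apart.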
